A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

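Transcript levels were measured in 10 shake-flask cultures of Saccharomyces cerevisiae, each hybridised as biotin-labelled RNA to a 1-colour Affymetrix yeast array. Per the labels, 3 strains were sampled during growth on 2% ethanol at 30 °C (time 0) and 30 min after 4% glucose had been added. CJM567 carried the genes TPK1, TPK2 and TPK3, which encode the catalytic subunits of protein kinase A (PKA). CJM571 lacked TPK1, TPK2, TPK3 and the kinase gene YAK1, and CJM569 lacked TPK1, TPK2, TPK3 and the genes of the stress transcription factors Msn2 and Msn4. CJM567 and CJM571 had 2 arrays per condition, numbered 1 and 2 in the labels, and CJM569 had 1. The labels do not say that arrays of one group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The growth protocol also describes a mixed condition for which no array was given, and it is not analysed here.

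The deposited values are 1 linear signal intensity per probe set and array. The submitters' processing notes name GCOS 1.2, and the summary algorithm and its settings are not given in the sources used here. The mean intensity after trimming 2% at each end lay between 150.1 and 150.2 on every array, so the deposited intensity values had been scaled to a common target near 150. Array medians lay between 33.6 and 49.2, and 28.3% to 34.1% of the probe sets per array were at or below an intensity of 12. The number of arrays limits the precision.

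Of 9335 probe sets, 60 were controls, 6504 had 1 gene in the platform annotation, 328 had several and 2503 had none. Only probe sets with 1 gene were named, all of them through the RefSeq gene table, which gave 5656 genes. For the 315 genes with several probe sets, the one with the highest mean log2 value was taken. TPK1 had no probe set of its own. Values under 12 were raised to 12 and log2-transformed, and 281 genes at this floor on all 10 arrays were left out, so that 5375 genes were tested. A fold change with one side at the floor is given as "at least".

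One linear model with a mean for each of the 6 groups was fitted per gene to all 10 arrays with limma 3.58.1 in R 4.3.3, followed by empirical Bayes moderation with an intensity trend (4 residual and 1.73 prior degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were the glucose response of each strain, the mean response of the strains without PKA, its difference from CJM567, the difference between CJM571 and CJM569, and the strain differences within each labelled condition. CJM569, with 1 array per condition, was assumed to vary like the other strains. The tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Comparisons between the replicate numbers, and of strains over all of their arrays, were added after the data had been seen. They came from a model with the replicate number within each strain as a block and the labelled condition as a term for each strain (2 residual and 2.39 prior degrees of freedom).

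For each comparison, the rule named the 10 genes with the highest and the 10 with the lowest log2 difference among called genes whose arrays did not overlap between the sides (5 and 5 for the comparisons of CJM571 with CJM569), up to 4 members of each described list, the targeted and marker genes, and any called glucose signalling component. Genes at the bottom of these rankings were left out of the text for length. Probe sets whose names mark shared sequence are pointed out as such.

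Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 26 lists within a comparison, and again with the correlation estimated from the residuals. No list passed with the estimated correlation in any comparison. That correlation rests on 4 residual degrees of freedom, or 2 with the block. Without the block, the residuals also hold the difference between the replicate numbers. Even the gluconeogenesis list, with every tested member lower between the numbers of CJM567, did not pass. Failing therefore does not show that a list was unchanged, and calls of lists rest on the preset correlation only. The lists were ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, gluconeogenesis and the glyoxylate cycle, the TCA cycle, the respiratory chain and ATP synthase, peroxisomal beta-oxidation, glycolysis and fermentation, hexose transporters, galactose, maltose and sucrose use, Msn2 and Msn4 stress targets, trehalose and glycogen metabolism, cytosolic chaperones, purine and pyrimidine synthesis, amino acid synthesis, nitrogen catabolite repressed genes, ergosterol synthesis, the proteasome, autophagy, the G1 to S transition, the iron and phosphate regulons, mating type and sporulation, cell wall and flocculation, glucose signalling components, and mitochondrial ribosomal proteins.

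The alternatives were quantile normalisation, division by the array median, floors of 32 and 1, a minimum mean intensity of 50, no filter, moderation without a trend, the mean of a gene's probe sets, a fit to the strains compared, the replicate number as a block within or across strains, each strain without PKA on its own, and leaving out each array of CJM567 and CJM571 in turn. The procedure was tested on simulated data with 200 changed genes among 5375, with noise drawn independently for each array. Real arrays of the same number deviated alike from their groups (r = 0.92 in CJM567 and 0.50 in CJM571), so the shares below need not hold for them. At true changes of 2-, 4-, 8- and 16-fold the procedure recovered 2%, 52%, 72% and 72% of 50 genes each for the response of CJM567, with 4 unchanged genes called. For the response of CJM569 it recovered 2%, 16%, 46% and 54%, with 10 unchanged genes called.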

Results

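The data set holds 10 arrays, 4 of CJM567, 4 of CJM571 and 2 of CJM569, with 1 linear intensity per probe set scaled to a trimmed mean near 150. It addresses which glucose effects on transcription do not need PKA, using suppressor mutations that allow growth without the kinase. The highest intensity per array lay between 5975 and 8917. The 3′ to 5′ ratio of the actin control lay between 0.868 and 1.55.

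Among the deleted genes, only MSN2 had a probe set whose signal followed the genotype in the labels. MSN2, a stress transcription factor gene, read 3.7 and 0.7 in CJM569 and 59.8 to 132 in the 8 libraries of the strains that kept it. MSN4 read 54.7 and 35.7 in CJM569, within its range of 26.8 to 73.7 elsewhere. TPK2 read 326 to 566 in the 6 libraries labelled as tpk2 mutants. In CJM567 it read 320 and 319 in the libraries numbered 1, and 27.5 and 27.1 in those numbered 2. TPK3 read 43.9 to 77.5 in the mutants and 35.3 to 68.2 in CJM567, and the brightest probe set of YAK1, which can share sequence with related genes, read 93.2 to 141 in CJM571. In CJM567 this YAK1 probe set read 242 and 284 in the libraries numbered 1, and 61.3 and 61.4 in those numbered 2. In CJM569 it read 145 in ethanol and 49.4 after glucose. Whether these probe sets lie inside the deleted parts is not known, so that their signal in a mutant does not decide whether the gene was deleted. The differences in TPK2 and YAK1 between the numbers of CJM567 lie within 1 labelled genotype and do not follow from it. Of the marker genes, HIS3 read 388 to 1832 in CJM567, where the libraries numbered 2 read 1832 and 1375, against 501 to 626 in CJM571 and 760 and 899 in CJM569. URA3 read 124 to 232 in CJM567, 259 to 349 in CJM571, and 130 and 258 in CJM569. TRP1 read 157 to 289, 207 to 350, and 443 and 269 in the same strains, and the brightest LEU2 probe set read 1174 to 1214, 1107 to 1754, and 1435 and 1010.

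In CJM567, the strain with PKA, genes of ethanol growth did not differ between the labelled conditions. FBP1, which encodes the gluconeogenic fructose-1,6-bisphosphatase, read 1754 and 1730 in the libraries labelled ethanol and glucose with number 1, and 17.2 and 34.2 in those with number 2. HXT1, a low-affinity glucose transporter gene, was at the floor in both libraries numbered 1 and read 1700 and 1990 in those numbered 2. The glucose response as labelled called 1 gene of 5375, SUF2, a tRNA gene whose probe set can share sequence with other genes (log2 difference 2.08 ± 0.10 SE, n = 2 per condition, limma adjusted p = 0.00858). It was at least 4.22-fold higher in the libraries labelled glucose, at a mean signal of 50.7. With the replicate number as a block within strain, SUF2 lost the call and no gene was called. An unadjusted p under 0.05 was reached by 117 genes in the fit without the block. Of the lists, ribosome biogenesis lay lower in the libraries labelled glucose (median log2 -0.33, 105 of 128 members below 0, none called, camera adjusted p = 6.10e-05, and adjusted p = 0.937 with an estimated correlation). The count was 10 without the library labelled glucose with number 1, and 0 without any one of the libraries labelled ethanol of CJM567 or any one of the 4 libraries of CJM571.

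In CJM571, the strain without PKA and Yak1, the labelled conditions did not separate genes of carbon metabolism either. FBP1 read 1400 and 1485 in the ethanol and glucose libraries numbered 1, and 39.0 and 55.7 in those numbered 2. HXT3, another low-affinity glucose transporter gene, read 163 and 124 against 1982 and 1850. No gene was called by limma, and 9 genes had an unadjusted p under 0.05. Ribosomal protein genes lay slightly higher in the libraries labelled glucose (median log2 0.10, 56 of 80 above 0, none called, camera adjusted p = 4.88e-04, and adjusted p = 0.992 with an estimated correlation).

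**Figure D1:**
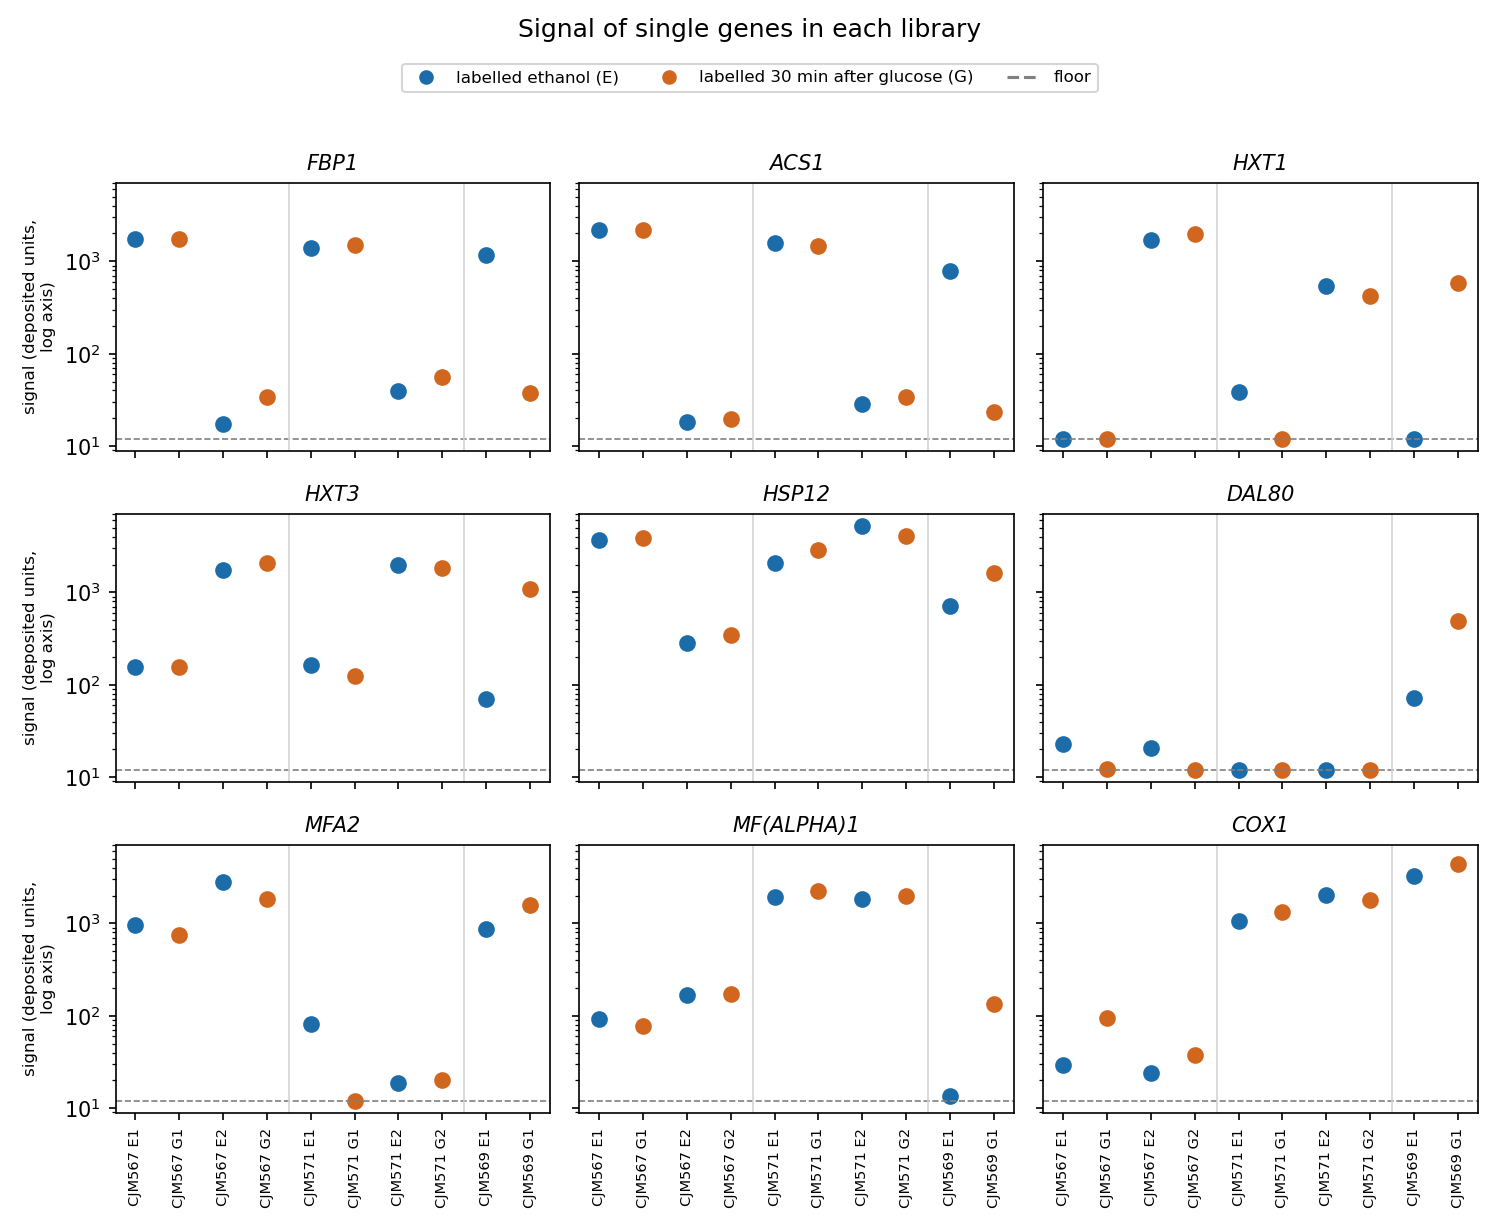
Signal of 9 genes in each of the 10 libraries, in deposited units on a log axis, with 1 point per library and no averaging; the dashed line is the floor of 12. FBP1, ACS1, HXT1 and HXT3 separate the replicate numbers of CJM567 and CJM571, and the labelled conditions of CJM569.

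The arrays of CJM567 and CJM571 differed by replicate number in the genes that distinguish growth on ethanol from growth on glucose. This comparison of number 2 with number 1, over the labelled conditions, was chosen after the data had been seen. Its SE and p measure the spread of arrays within a number. If a number marks a single culture or batch, arrays of the same number are not replicates of the difference. In CJM567, ACS1, encoding an acetyl-CoA synthetase, averaged 19.0 in the libraries numbered 2 and 2176 in those numbered 1 (log2 -6.84 ± 0.18, n = 2 per number, adjusted p = 0.00197). FBP1 was lower by 71.8-fold (-6.17 ± 0.30), and the carnitine and acetate genes CAT2 (-6.14), ADY2 (-5.93), ACH1 (-5.82) and CRC1 (-5.79) were lower as well. HXT1 was at least 153-fold higher in the libraries numbered 2 (7.26 ± 0.37), HXT3 12.2-fold (3.61 ± 0.17) and the pyruvate decarboxylase gene PDC5 38.3-fold (5.26 ± 0.53).

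In total 2115 genes were called between the numbers in CJM567, 692 higher and 1423 lower in number 2. TPK2 (-3.55 ± 0.27) and HIS3 (1.98 ± 0.15) were among them, and whether the libraries of both numbers come from 1 strain is not known, which limits each comparison with CJM567. All 17 tested genes of gluconeogenesis and the glyoxylate cycle were lower (median -5.50, 17 adjusted over the list alone), as were 15 of 16 TCA cycle genes (median -2.69, 15 over the list alone), 13 of 19 beta-oxidation genes (median -2.27, 14 over the list alone, with 1 higher) and 39 of 43 mitochondrial ribosomal protein genes (median -1.48, 41 over the list alone). Stress targets of Msn2 and Msn4 were lower in 51 of 57 cases (median -2.78, 52 over the list alone), among them SIP18 (-5.45) and GRE1 (-5.42), and all 19 trehalose and glycogen genes were lower (median -2.49, 19 over the list alone). Ribosome biogenesis genes were higher in 81 of 128 cases (median 1.04, 99 over the list alone), ribosomal protein genes in 39 of 80 (median 0.69, 43 over the list alone), genes of RNA polymerases I and III in 9 of 35 (median 0.55, 8 over the list alone) and amino acid synthesis genes in 44 of 65 (median 1.31, 48 over the list alone, with 3 lower). These lists had camera adjusted p between 6.70e-23 and 9.25e-04 and adjusted p of 0.133 to 0.136 with an estimated correlation.

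Another 8 lists passed camera in CJM567. Respiratory chain genes were lower in 19 of 34 cases (median -0.87, 23 adjusted over the list alone), genes of galactose, maltose and sucrose use in 6 of 10 (median -1.80, 6 over the list alone), autophagy genes in 9 of 18 (median -0.92, 10 over the list alone) and proteasome genes in 7 of 33 (median -0.57, 5 over the list alone). Glycolysis and fermentation genes had 6 higher and 1 lower of 18 (median 0.58, 6 and 1 over the list alone), purine and pyrimidine synthesis 11 and 3 of 29 (median 0.63, 12 and 3 over the list alone), the phosphate regulon 5 and 2 of 14 (median 0.58, 8 and 2 over the list alone), and mating type and sporulation 9 and 4 of 21 (median 0.52, 9 and 4 over the list alone). These 8 lists had camera adjusted p between 3.49e-05 and 0.0311, and adjusted p of 0.133 to 0.441 with an estimated correlation. The remaining lists passed neither camera test. Their medians were -0.08 for hexose transporters (3 higher and 3 lower of 9), 0.01 for ergosterol synthesis, 0.02 for cell wall and flocculation, 0.22 for nitrogen catabolite repressed genes (5 higher and 6 lower of 26), -0.46 for the iron regulon (7 lower of 25), -0.65 for the G1 to S transition (2 higher and 11 lower of 29), and -0.25 for cytosolic chaperones, a sign that turned with quantile normalisation (0.03) and with median scaling (0.25). The means of nitrogen catabolite repressed genes (-0.17), ergosterol synthesis (-0.07) and cell wall and flocculation (-0.10) lay below 0 against medians above it, and the test pointed up for these 3 lists, for hexose transporters (mean 0.04) and for cytosolic chaperones. Of 56 glucose signalling components (median -0.52), 25 were called. MIG2 (2.97), STD1 (2.59), MIG3 (2.01) and NRG1 (1.55), which encode regulators of glucose-repressed and glucose-induced genes, were higher in number 2. SIP4 (-3.58), CAT8 (-2.81) and HAP4 (-2.35), activators of genes for non-fermentable carbon use, were lower, as were the sensor gene SNF3 (-2.47), MTH1 (-1.76), and the Ras and PKA pathway genes RAS2 (-2.06), BCY1 (-1.94), RIM15 (-1.90) and GIS1 (-1.80). Besides cytosolic chaperones, the medians of 16 lists moved by over 1.5 times with the scaling. With quantile normalisation and median scaling they were 0.29 and 1.2 for ribosomal proteins, 0.86 and 1.06 for RNA polymerases I and III, 0.19 and 1.08 for glycolysis and fermentation, 0.45 and 1.13 for purine and pyrimidine synthesis, 0.68 and 1.09 for the phosphate regulon, and 0.86 and 1.02 for mating type and sporulation. They were 0.44 and 0.72 for nitrogen catabolite repressed genes, 0.14 and 0.52 for ergosterol synthesis, and 0.01 and 0.52 for cell wall and flocculation. Among lists below 0 they were -0.93 and -0.36 for the respiratory chain, -1.19 and -0.98 for mitochondrial ribosomal proteins, -0.43 and -0.06 for the proteasome, -0.28 and -0.02 for the G1 to S transition, -0.26 and 0 for the iron regulon, -0.08 and -0.23 for hexose transporters, and -0.17 and -0.02 for glucose signalling components. The median of all genes was -0.21 in this comparison, 0.02 after quantile normalisation and 0.21 after median scaling. The split of 692 higher and 1423 lower became 970 and 1036, and 1411 and 853, in those fits.

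In CJM571, 88 genes were called between the numbers, 24 higher and 64 lower in number 2. ACS1 averaged 31.4 against 1510 (log2 -5.59 ± 0.18, adjusted p = 0.00853), FBP1 47.4 against 1442 (-4.95 ± 0.30), and REG2, a regulatory subunit gene of protein phosphatase 1, 15.4 against 823 (-5.74). HXT3 was 13.5-fold higher (3.75 ± 0.17) and HXT1 higher by log2 4.48 ± 0.37, with 1 library numbered 1 at the floor. GPP2 (3.84), a glycerol phosphatase gene, STD1 (2.58) and YGP1 (2.78), a secreted glycoprotein gene induced in starvation, were also higher, and CAT8 (-2.45) and SIP4 (-3.59) were lower. Gluconeogenesis genes were lower in 15 of 17 cases (median -4.03, 17 adjusted over the list alone), beta-oxidation genes in 6 of 19 (median -0.89, 10 over the list alone) and the TCA cycle gene CIT3 (-3.88) alone of 16 (median -0.54, 4 over the list alone). No ribosome biogenesis gene was called, at a median of 0.38 with 115 of 128 above 0. Of the stress targets of Msn2 and Msn4, 2 were higher and 1 lower of 57 (median 0.02, and -0.01 after median scaling, with 5 and 6 over the list alone). Of the 26 lists, 14 passed camera, each with an adjusted p of 0.212 to 0.432 with an estimated correlation. The stress target list did not pass (camera adjusted p = 0.902).

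The number difference itself differed between the strains, in 569 genes, of which 444 were higher and 125 lower in CJM571 than in CJM567. The stress targets GRE1 (5.78 ± 0.29), SIP18 (5.73 ± 0.29), HSP26 (5.35 ± 0.24) and GPD1 (5.0 ± 0.39), each with an adjusted p of 0.0199, were lower in number 2 of CJM567 and not in number 2 of CJM571. Of the 57 stress targets, 41 were higher (median 2.71, 50 adjusted over the list alone), as were 11 of 19 trehalose and glycogen genes (median 1.95, 17 over the list alone) and 11 of 16 TCA cycle genes (median 1.89, 12 over the list alone). PDC5 (-5.94 ± 0.75) and the arginine genes ARG3 (-4.15 ± 0.34) and ARG1 (-3.44 ± 0.34) were lower, with 15 of 65 amino acid synthesis genes (median -0.93, 30 over the list alone, with 1 higher). These lists had camera adjusted p between 3.98e-18 and 2.25e-05, and adjusted p = 0.158 with an estimated correlation. Genes called between the numbers in both strains and chosen after their values had been seen, FBP1 (difference 1.21, adjusted p = 0.143), ACS1 (1.25, adjusted p = 0.0538) and HXT3 (0.14, adjusted p = 0.717), were not called for a difference. After quantile normalisation the split of 444 and 125 was 253 and 151, and after median scaling 204 and 280, around a median of all genes of 0.21, -0.04 and -0.25. The median of amino acid synthesis genes moved from -0.93 to -0.77 and -1.47 in those fits.

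With the number as a block the fit has 2 residual degrees of freedom. Leaving out any one of the 4 libraries of CJM567 left no called gene in any of these 3 comparisons, and leaving out any one of CJM571 left none in CJM571 or in the difference. Without the labelled condition in the model, 2200, 177 and 832 genes were called in CJM567, in CJM571 and for the difference, and single left-out libraries gave 1411 to 2206, 59 to 141 and 363 to 637. The 59 and the 363 came without the library of CJM571 labelled glucose with number 1. In CJM571, counts of 138 and 141 came without the CJM567 libraries numbered 2 labelled ethanol and glucose.

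In CJM569, the strain without PKA, Msn2 and Msn4, FBP1 read 1157 in the library labelled ethanol and 37.8 in that labelled glucose, and HXT3 69.8 and 1098, without a call in the fit to the 6 groups. With 1 array per condition, the SE and p of each gene below come wholly from the spread between libraries of CJM567 and CJM571. CJM569 is assumed to vary like these strains. Where a gene lies near the floor of 12 in them, raising values to the floor holds this spread down. For FBP1 and HXT3 the differences between the numbers widen it. Which genes are called in CJM569 therefore depends on the source of the spread. Among the genes called higher 30 min after glucose were 4 under nitrogen catabolite repression. The allantoin permease gene DAL4 read 538 against 34.0 in ethanol (log2 3.99 ± 0.36, adjusted p = 0.0157), and DAL1, which encodes allantoinase, was at least 14.4-fold higher, at a signal of 172 (adjusted p = 0.0150). UGA4, a GABA permease gene, was 9.07-fold higher (3.18 ± 0.32) and the regulator gene DAL80 6.76-fold (2.76 ± 0.19). FIT1, a cell wall mannoprotein gene of the iron regulon, was lower (-3.33 ± 0.28, adjusted p = 0.0133), and the sporulation gene CDA2 lower by at least 11.8-fold (-3.56 ± 0.27).

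The test in CJM569 called 23 genes, 8 higher and 15 lower. The others included SDL1 (1.96), EDC1 (1.04), SUF6 (1.98) and SAE3 (0.82), the last 2 from probe sets that can share sequence, and among lower genes YMR316C-A (-4.09), DMC1 (-1.58), DFP3 (-1.50) and BAG7 (-1.05). Nitrogen catabolite repressed genes had 4 of 26 higher (median 0.66, 9 adjusted over the list alone, camera adjusted p = 1.14e-06, adjusted p = 0.107 with an estimated correlation). The iron regulon had 1 of 25 lower (median -1.05, 4 over the list alone, 24 below 0, camera adjusted p = 5.79e-12, adjusted p = 0.628 with an estimated correlation). Gluconeogenesis genes lay below 0 in 17 of 17 cases (median -4.14), led by SFC1 (-5.47), CRC1 (-5.20), ADY2 (-5.15) and ACS1 (-5.07), without a single member called over all genes or over the list alone. The medians of ribosome biogenesis (0.75, 120 of 128 above 0), ribosomal proteins (0.38), RNA polymerases I and III (0.51), the G1 to S transition (0.38), the proteasome (-0.43) and beta-oxidation (-0.82) also passed camera with no member called. For these 7 lists the camera adjusted p lay between 1.24e-08 and 0.0440, and the adjusted p was 0.828 with an estimated correlation.

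The response of CJM569 had no replicate check of its own, and its count depended on the spread in the other strains. It was 8 without the library labelled ethanol with number 1 or the one with number 2 of CJM567. Of the CJM571 libraries, leaving out ethanol 1 gave 13, glucose 1 gave 13, ethanol 2 gave 12 and glucose 2 gave 3. With the replicate number within strain as a block, 160 genes were called in CJM569, 60 higher and 100 lower. They included 15 of 17 gluconeogenesis genes (17 over the list alone), HXT1 (5.59 ± 0.52, at least 48.3-fold higher) and HXT3 (3.98 ± 0.23), and 16 lists passed camera, none with an estimated correlation.

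Called genes were shared between the labelled CJM569 response with the block and the number differences of the other strains. Of the 60 genes higher after glucose in CJM569, 29 were higher in number 2 of CJM567 and 6 in number 2 of CJM571, where independent lists would share 7.73 and 0.268. Of the 100 lower genes, 61 and 40 were lower in number 2, against 26.5 and 1.19. The 3 comparisons share 1 variance estimate per gene, which by itself can raise the overlap above that of independent lists. In all 3 comparisons 5 genes were higher, FSH1, HXT1, HXT3, SOL3 and YLR108C (FSH1 and SOL3 named after their values had been seen), and 38 were lower, among them ACS1, FBP1, PCK1, ICL1, MLS1 and the regulator genes CAT8 and SIP4. Across the 5375 genes, which are not independent replicates, the CJM569 response had a Pearson correlation of 0.51 with the number difference of CJM567 and 0.55 with that of CJM571. Its correlation with the labelled responses of these strains was 0.017 and -0.13. With 1 and 0 labelled calls in CJM567 and CJM571, their overlap of 0 with CJM569 in the fit without the block carries no information.

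**Figure D2:**
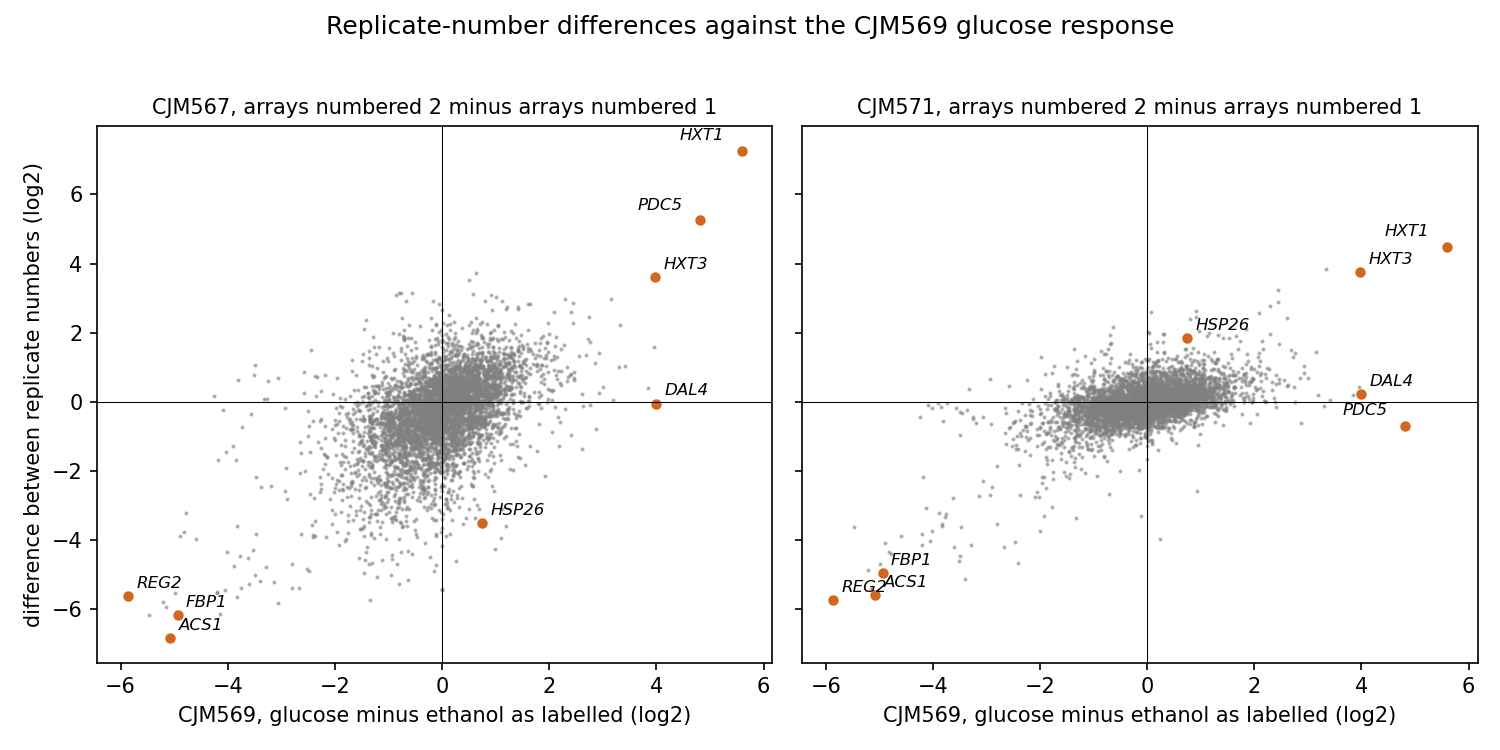
Log2 difference between arrays numbered 2 and 1 of CJM567 (left) and CJM571 (right) against the log2 difference between the labelled conditions of CJM569, with 1 grey point per gene for 5375 genes and 8 genes named. REG2, FBP1, ACS1, HXT1 and HXT3 lie in the same corners in both panels, and HSP26 and PDC5 lie on opposite sides of 0.

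The mean glucose response of the strains without PKA, which addresses effects that do not need the kinase, followed CJM569. DAL4 (1.94 ± 0.22), UGA4 (1.84 ± 0.19), DAL1 (1.83 ± 0.21) and DAL80 (1.38 ± 0.12) were higher, and FIT1 (-1.73 ± 0.17) was lower, with adjusted p from 0.0309 to 0.0486. YMR316C-A (-1.91 ± 0.15) and CDA2 (-1.76 ± 0.16), named after their values had been seen, were lower as well. In total 16 genes were called, 6 higher and 10 lower. The count was 2 after quantile normalisation (1 and 1) and 6 after median scaling (1 and 5). It was 0 in CJM571 alone, where DAL4 (-0.11) and DAL1 (-0.19) had the opposite sign, and 23 in CJM569 alone. Leaving out any one of the 8 libraries of CJM567 and CJM571 gave 0. Of the lists, 9 passed camera, among them nitrogen catabolite repressed genes (4 of 26 called, median 0.33, 6 adjusted over the list alone), gluconeogenesis (median -1.99, none called) and the iron regulon (1 of 25 called, median -0.71, 2 over the list alone). The adjusted p of the 9 lay between 0.0900 and 0.799 with an estimated correlation.

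Between the glucose response without PKA and that of CJM567 no gene was called by limma, and 211 had an unadjusted p under 0.05. For the mean of the strains without PKA, ribosome biogenesis lay higher (median 0.75, 118 of 128 above 0, camera adjusted p = 1.05e-11) and gluconeogenesis lower (median -2.16, 17 of 17 below 0, camera adjusted p = 0.0448), with adjusted p of 0.817 and 0.843 with an estimated correlation and no member called. ADY2 (-3.27), YAT2 (-2.84) and FBP1 (-2.80) had the lowest values of the gluconeogenesis list, each with an adjusted p of 1.00. CJM569 alone carried the gluconeogenesis difference, with response medians of -4.14 in CJM569, 0.28 in CJM571 and 0.17 in CJM567. For ribosome biogenesis the medians were 0.75, -0.05 and -0.33 in the same strains. These differences rest on labels of CJM567 and CJM571 that did not separate the same genes. For CJM569 alone against CJM567 the count was 14.

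The glucose responses of CJM571 and CJM569, which differ in the suppressor mutation, differed in 14 genes, 9 higher and 5 lower in CJM571. YMR316C-A (4.36 ± 0.31), CDA2 (3.60 ± 0.33), FIT1 (3.20 ± 0.34), DMC1 (1.58 ± 0.11) and DFP3 (1.44 ± 0.13) were higher in CJM571. DAL4 (-4.10 ± 0.43), DAL1 (-4.04 ± 0.41), DAL80 (-2.76 ± 0.24), SDL1 (-1.96 ± 0.13) and EDC1 (-1.04 ± 0.11) were lower. The adjusted p of these genes lay from 0.0197 to 0.0430. For DAL80, SDL1, EDC1 and DMC1 the size equalled that of the CJM569 response, so CJM571 showed no measured response. DAL80 lay at the floor in CJM571 after glucose, and DAL1 in CJM569 in ethanol. Their sizes depend on the floor, and values held at the floor keep the SE small. For such genes the test does not compare measured responses of both strains. Of the lists, gluconeogenesis (median 4.30, none called), the iron regulon (0.95, 1 of 25 higher, 3 adjusted over the list alone), nitrogen catabolite repressed genes (-0.87, 3 of 26 lower, 7 over the list alone), ribosome biogenesis (-0.85, none called) and the G1 to S transition (-0.26, none called) passed camera, with adjusted p of 0.114 to 0.864 with an estimated correlation. The count of 14 was 2 after quantile normalisation (1 and 1) and 6 after median scaling (5 and 1), which lowered the median of all genes from 0.00 to -0.10. It was 25 with the replicate block within strain, and 0 or 1 without any one library of CJM567 or CJM571. EDC1 turned to 0.34 with a floor of 1.

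In the libraries labelled ethanol, the strains without PKA differed from CJM567 in 19 genes, all higher. The mitochondrially encoded COX1 averaged 2109 against 26.9 (log2 6.35 ± 0.51, adjusted p = 0.0217), and the iron regulon genes FIT1 (2.06 ± 0.18) and FRE3 (0.88 ± 0.07) were the only called members of their list (2 of 25, median 0.78, 2 adjusted over the list alone). CJM569 alone carried the calls of FIT1, at 222 against 12 and 16.9 in CJM571 and 12.7 and 14.3 in CJM567, and of FRE3, at 42.6 against the floor in CJM571 and 12.6 or less in CJM567. Ribosome biogenesis (median -1.31, 128 of 128 below 0), ribosomal proteins (-0.64) and nucleotide synthesis (-0.76) lay lower and the proteasome (0.59, 33 of 33 above 0) and autophagy (0.68) higher without a called member. These 6 lists and 4 others passed camera, with adjusted p of 0.777 to 0.899 with an estimated correlation. In the ethanol-labelled libraries of CJM567 and CJM571, FBP1 was high with number 1 and low with number 2, whereas it was high in CJM569. The sides thus held unlike shares of libraries with high FBP1, and the gluconeogenesis list had a median of 1.695. List differences here cannot be told apart from this imbalance. The count was 6 after quantile normalisation. It was 4 without the CJM567 library labelled glucose with number 1, 3 without that with number 2, and 0 without any other single library of CJM567 or CJM571. Median scaling shifted the median of all genes from 0.06 to -0.07.

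In the libraries labelled glucose, 21 genes differed between the strains without PKA and CJM567, 14 higher and 7 lower. COX1 (5.44 ± 0.51), DAL80 (2.65 ± 0.13), UGA4 (2.57 ± 0.21) and DAL4 (2.13 ± 0.23) were higher, with adjusted p from 0.00568 to 0.0350. COX1 lay higher in both strains, whereas CJM569 alone carried DAL80 (484 against the floor in CJM571), UGA4 (579 against 14.9 and 19.2) and DAL4 (538 against 30.3 and 38.5). Over all arrays, the median difference of the nitrogen catabolite repressed list from CJM567 was -0.55 for CJM571 and 0.85 for CJM569. The tRNA genes SUP19 (-2.82), SUF10 (-2.23), SUP51 (-2.13) and SUF2 (-1.40) were among the lower genes, all from probe sets that can share sequence. The split of 14 and 7 became 7 and 0 after quantile normalisation and 9 and 0 after median scaling, which shifted the median of all genes from 0.07 to -0.04. Nitrogen catabolite repressed genes (3 of 26 called, median 0.40, 5 adjusted over the list alone), the phosphate regulon (median -0.70) and ribosome biogenesis (median -0.64) were among 8 lists that passed camera, with adjusted p of 0.347 to 0.944 with an estimated correlation. Of the CJM567 libraries, leaving out ethanol 1 gave 4, ethanol 2 gave 9 (4 higher and 5 lower), glucose 2 gave 7 (3 and 4) and glucose 1 gave 20 (6 and 14), so that the excess of higher genes turned in the last 3. Of the CJM571 libraries, ethanol 1 or ethanol 2 gave 3, and glucose 1 or glucose 2 gave 0. In the glucose-labelled libraries of CJM567 and CJM571, FBP1 again differed between the numbers, whereas it was low in CJM569. The gluconeogenesis list had a median of -0.60. List differences here cannot be told apart from unlike shares of libraries with high FBP1.

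Between CJM571 and CJM569 in the libraries labelled ethanol, 46 genes differed, 5 higher and 41 lower in CJM571. The mating pheromone gene MF(ALPHA)1 read 1924 and 1846 in CJM571 and 13.7 in CJM569, and was called. AFB1, an alpha-specific gene, was at least 24.5-fold higher (4.61 ± 0.34). FRE3 lay at the floor in CJM571, and DAL80 and UGA4 at or next to it, so that their log2 differences below are least sizes. HMRA1, from a probe set that can share sequence, was lower (-5.27 ± 0.43), as were the iron regulon genes FIT1 (-3.96 ± 0.24) and FRE3 (-1.83 ± 0.09), with 2 of 25 called (median -1.75, 11 adjusted over the list alone), and DAL80 (-2.58 ± 0.17) and UGA4 (-2.41 ± 0.27), with 2 of 26 nitrogen catabolite repressed genes called (median -0.88, 6 over the list alone). These lists were among 8 that passed camera, with adjusted p of 0.0608 to 0.885 with an estimated correlation. FBP1 differed between the numbers of CJM571 and was high in CJM569. Gluconeogenesis had a median of -1.98 and ribosome biogenesis of 1.006. List differences here cannot be told apart from unlike shares of libraries with high FBP1. The count was 29 without the CJM567 library labelled ethanol with number 1. Of the CJM571 libraries, ethanol 1 gave 26, ethanol 2 gave 24 and glucose 1 or glucose 2 gave 29.

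Mating-type genes separated CJM571 from the other strains in all of its libraries, although the labels give all strains as MATa. The a-factor gene MFA2 read 12 to 81.5 in CJM571, 742 to 2792 in CJM567, and 860 and 1569 in CJM569. The a-specific receptor gene STE2 was at the floor in CJM571 and read 47.6 to 379 in CJM567. MF(ALPHA)1 read 1846 to 2250 in CJM571 against 78.2 to 170 in CJM567, and the alpha-specific genes STE3 and AFB1 read 87.3 to 170 and 290 to 347 against 12 to 20.9 and 13.6 to 20.7. SAG1 and MF(ALPHA)2, also alpha-specific, overlapped between the strains.

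Over all arrays, a comparison chosen after the data had been seen, CJM571 differed from CJM567 in 1140 genes, 765 higher and 375 lower. COX1 was 37.7-fold higher (5.24 ± 0.22) and ALD4, of the gluconeogenesis list, 4.86-fold (2.28 ± 0.20). The ergosterol gene ERG24 was 3.09-fold higher (1.63 ± 0.13), with 12 of 23 ergosterol genes higher (median 0.67, 17 adjusted over the list alone). Of the stress targets, 30 of 57 were higher and 5 lower (median 0.87, 33 and 7 over the list alone), and of the trehalose and glycogen genes 13 and 1 of 19 (median 0.94, 14 and 1 over the list alone). Both lists had unlike number differences in the strains. The medians were -2.78 in CJM567 and 0.02 in CJM571 for stress targets, and -2.49 and -0.46 for trehalose and glycogen genes. Their strain averages therefore need not hold within each number. Ribosome biogenesis genes were lower in 50 of 128 cases (median -0.71, 86 over the list alone), among them NSR1 (-1.87) and DBP2 (-1.46). MFA2 (-5.81 ± 0.49) and AGA2 (-4.26 ± 0.19), a mating agglutinin gene, and the adenine deaminase gene AAH1 (-3.60 ± 0.17) had low values. Of the lists, 19 passed camera, with adjusted p of 0.147 to 0.424 with an estimated correlation. The split of 765 and 375 was 516 and 418 after quantile normalisation and 432 and 593 after median scaling, around a median of all genes of 0.14, 0.02 and -0.04. Without the block, the count was 18 (7 higher and 11 lower), and leaving out any one library of CJM567 or CJM571 in the fit with the block gave 0. With the labelled condition out of the model it was 687 without the CJM571 library labelled ethanol with number 1, and 750 without that labelled glucose with number 1.

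CJM569 differed from CJM567 in 933 genes over all arrays, 406 higher and 527 lower. COX1 (6.55 ± 0.27) and the mitochondrially encoded OLI1 (2.84 ± 0.16) were higher, as were the iron regulon genes FIT2 (4.13 ± 0.36), TIS11 (3.65 ± 0.26) and FIT3 (3.59 ± 0.26), with 14 of 25 members called (median 0.79, 18 adjusted over the list alone). Nitrogen catabolite repressed genes were higher in 12 of 26 cases and lower in 1 (median 0.85, 17 and 1 over the list alone), led by DAL80 (3.52 ± 0.11) and UGA4 (3.49 ± 0.19). YGP1 (-4.62 ± 0.20), GRE1 (-2.83 ± 0.18) and SIP18 (-2.73 ± 0.18) were lower, with 20 of 57 stress targets lower and 6 higher (median -0.32, 20 and 9 over the list alone), and ribosome biogenesis genes were lower in 80 of 128 cases (median -1.21, 109 over the list alone). Within CJM567 the stress targets were lower in number 2 (median -2.78), GRE1 and SIP18 among them. Strain averages of these genes therefore need not hold against each number of CJM567. Of the lists, 13 passed camera, with adjusted p of 0.224 to 0.369 with an estimated correlation. The count was 59 without the block (50 higher and 9 lower) and 0 without any one library of CJM567 in the fit with the block. The 25S rRNA control probe set read 4030 and 3608 in CJM569 and 97.0 to 383 in the other libraries.

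**Figure D3:**
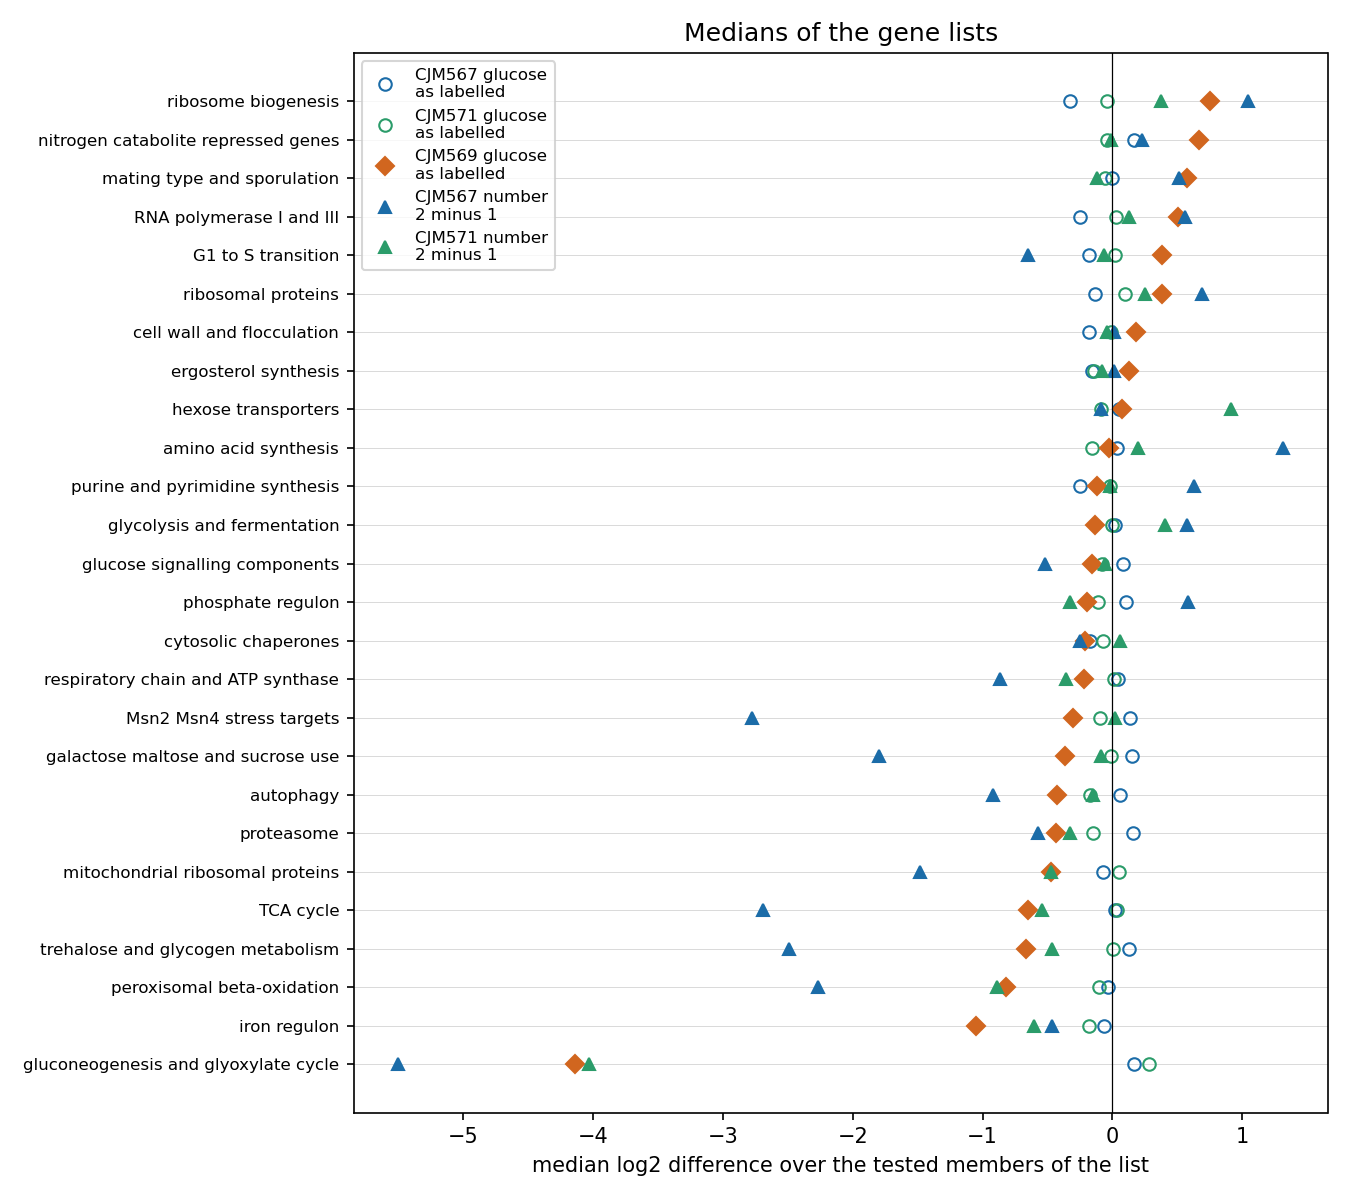
Median log2 difference of the tested members of each of the 26 gene lists, for the labelled glucose responses of CJM567 and CJM571 (circles) and CJM569 (diamonds) and for number 2 minus number 1 in CJM567 and CJM571 (triangles), from the deposited values. Gluconeogenesis lies at -4.14 in CJM569 and at -5.50 and -4.03 between the numbers, against 0.17 and 0.28 for the labelled responses, and the median of cytosolic chaperones between the numbers of CJM567 turned sign with the scaling.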

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

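All tests of explanations below were chosen after the result had been seen. The first result is the difference between the replicate numbers, singled out because a test of the difference between strains called 569 genes. GRE1 (5.78), SIP18 (5.73), HSP26 (5.35), HXT5 (5.10) and GPD1 (5.0) had a higher number difference in CJM571 than in CJM567, and PDC5 (-5.94), ARG3 (-4.15), ARO5 (-4.03), YMC2 (-3.63) and ARG1 (-3.44) a lower one.

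In both strains the numbers, and not the labelled conditions, separated FBP1, ACS1, HXT1 and HXT3, and no library was reassigned. Exchanged labels of sample groups would give a number difference like the glucose response of CJM569, and across 5375 genes, which are not independent replicates, the correlation was 0.51 for CJM567 and 0.554 for CJM571. An array batch should give no preferred sign among the 160 genes called in CJM569 with the block, but 74.4% (95% interval 66.9% to 80.9%) and 80.0% (73.0% to 85.9%) had the same sign, so that a batch alone is unlikely, with the reserve that genes are not independent. Cultures in another carbon state than labelled would give the same median of the gluconeogenesis list (-5.50), and the data cannot separate this from exchanged labels. Another strain in the libraries numbered 2 of CJM567 was not tested. MSN2 read 80.8 and 59.8 there, against 3.7 and 0.7 in CJM569. All 6 a-specific genes read at least 98 there, against at most 81.5 in CJM571. COX1 read 24.2 and 37.4, against 1068 to 2034 in CJM571 and 3226 and 4347 in CJM569. These values argue against CJM571 or CJM569 as their source, but a strain outside the series stays open. TPK2 read 27.5 and 27.1 in the libraries numbered 2 of CJM567, against 320 and 319 in those numbered 1. Another strain would change the meaning of the 2115 and 569 genes and of each comparison with CJM567. YAK1 read 61.3 and 61.4 against 242 and 284, but it also fell in CJM569, from 145 in ethanol to 49.4 after glucose. A lower YAK1 signal is therefore not particular to those libraries of CJM567.

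A test of the difference between the glucose responses of CJM571 and CJM569 called 14 genes. YMR316C-A (4.36), CDA2 (3.60), FIT1 (3.20), DMC1 (1.58) and DFP3 (1.44) lay higher in CJM571, and DAL4 (-4.10), DAL1 (-4.04), DAL80 (-2.76), SDL1 (-1.96) and EDC1 (-1.04) lower. For DAL80, SDL1, EDC1 and DMC1 the difference had the size of the CJM569 response alone. DAL80 lay at the floor in CJM571 after glucose, and DAL1 in CJM569 in ethanol, so their sizes depend on the floor. If the labels of CJM571 do not mark the carbon source, this test does not compare 2 glucose responses, and an effect of the suppressor was neither shown nor excluded.

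CJM571 expressed alpha-specific genes although it is labelled MATa. A mixture of a and alpha cells would keep a-specific transcripts, but the median of 6 a-specific genes was -3.91 against CJM567, which does not favour a mixture. A strain of the other mating type would raise the alpha-specific genes, and their median was 3.12 over 5 genes, with SAG1 and MF(ALPHA)2 not called. The mating type may therefore differ from the label, which would add to any strain difference between CJM571 and the other strains.

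The 25S rRNA control probe set, which no comparison used, read 4030 and 3608 in the CJM569 libraries labelled ethanol and glucose, above the other 8 libraries. RNA without poly(A) tails carried into these samples could raise it, and would raise small nucleolar and spliceosomal RNAs too, whose median was 0.21 over 42 genes, too small to decide. Many of these small RNAs lay at or near the floor, so their low median excludes nothing. All 9 tested mitochondrial-genome transcripts lay higher in CJM569 than in CJM567 (median 2.10). Among them, COX2 and ATP8 read 15.2 or less in CJM569 and were not called, and VAR1 was at the floor there after glucose. COX1 was also higher in CJM571, where the 25S probe set was not higher than in CJM567 (mean log2 -0.54). That value leans on the CJM571 glucose library numbered 1, at 97.0. The other CJM571 libraries read 264 to 367, against 296 to 383 in CJM567. Such RNA is therefore an unlikely source of COX1 in CJM571.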

How the results depend on the processing

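The settings for the replicate numbers, for strains over all arrays and for selected libraries were chosen after seeing the data. Named genes kept direction and side of the threshold in 26086 comparisons, lost the call in 4743, gained it in 130 and reversed in 3. Those 3 were DAL4 (-0.11) and DAL1 (-0.19) with CJM571 alone for the mean response, and EDC1 (0.34) with a floor of 1 for CJM571 minus CJM569. Gene lists stayed the same in 2676 comparisons, lost the call in 184 and gained it in 52. Of the counts, 158 stayed within 1.5 times and 164 moved. Except where fewer arrays or genes were used, the cause was not tested.

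The count for CJM567 (1) was 5 without a filter and 0 with quantile normalisation, median scaling, either floor, the intensity minimum, no trend, or only its own strain. The count for CJM569 (23) was 8 with quantile normalisation, 52 with a floor of 32, 66 without a filter, and 0 with a floor of 1, the minimum or no trend. The mean without PKA (16) gave 2 with quantile normalisation, 6 with median scaling, 36 with a floor of 32, 60 without a filter, 9 with the mean of probe sets, and 0 with a floor of 1, the minimum, no trend, only its strains or CJM571 alone. Its difference from CJM567 (0) gave 19 with a floor of 32, 46 without a filter and 14 with CJM569 alone. CJM571 minus CJM569 (14) gave 2, 6, 38, 57 and 9 with quantile normalisation, median scaling, a floor of 32, no filter and the mean of probe sets, and 0 with a floor of 1, the minimum, no trend or only its strains. Ethanol without PKA (19) gave 6 with quantile normalisation, 39 with a floor of 32, 54 without a filter, 1 with the minimum, and 0 with a floor of 1 or no trend. Ethanol CJM571 minus CJM569 (46) gave 3 with a floor of 1, 3 with the minimum and 14 with no trend. Glucose without PKA (21) gave 7 with quantile normalisation, 9 with median scaling, 48 without a filter, 1 with no trend, and 0 with a floor of 1 or the minimum. The overlap of labelled calls (0) was 2 without a filter.

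Arrays with the same number deviated alike from their groups (r = 0.916 in CJM567, 0.501 in CJM571), and the number differences of CJM567 and CJM571 correlated at 0.539 across genes, which are not independent replicates. The labels do not say what a number marks. Part of the genes called for the mean without PKA lost the call with the number as a block within strain. With the replicate number as a block within strain, the labelled counts were 0 for CJM567, 160 for CJM569 and 25 for CJM571 minus CJM569. With a block across strains they were 7 for the mean without PKA, 8 for CJM571 minus CJM569 and 11 for ethanol without PKA.

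Between the numbers, CJM567 (2115) kept its count outside single left-out libraries. CJM571 (88) gave 58 with a floor of 32, 184 with a floor of 1, 258 with the minimum, 21 without a filter and 177 without the labelled condition. The difference (569) gave 253, 936, 910 and 142 with the first 4 of these. Over all arrays, CJM571 minus CJM567 (1140) gave 744 without a filter and 18 without the block, and CJM569 minus CJM567 (933) gave 580 and 59.

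Leaving out single libraries gave 0 to 10 for CJM567, 3 to 22 for CJM569, 0 to 0 for the mean without PKA, 0 to 1 for CJM571 minus CJM569, 0 to 4 for ethanol without PKA, 24 to 38 for ethanol CJM571 minus CJM569, 0 to 20 for glucose without PKA and 0 to 2 for the overlap. For the numbers it gave 0 to 2206 in CJM567, 0 to 141 in CJM571 and 0 to 637 for the difference, and over all arrays 0 to 1114 for CJM571 and 0 to 1082 for CJM569. A lone array was assumed to vary like the other groups, and the 0 in the fits with the block came with 1 residual degree of freedom.

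With only the ethanol-labelled libraries 1 and the glucose-labelled libraries 2 of CJM567 and CJM571, no test was made, and genes at least 2-fold apart numbered 2036 for CJM567 (81 with all libraries), 347 for CJM571 (11), 443 for the mean without PKA (185), 1706 for its difference from CJM567 (473), 467 for ethanol (854) and 1466 for glucose without PKA (386). The libraries were picked on these genes, so the rise is by construction. Between 28.3% and 34.1% of probe sets per array were at or below the floor, which limits changes among weak signals.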

Other observations

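The split of arrays for the mean response was chosen before the result was seen, and that for CJM571 against CJM567 after it. In a 2-group fit of the 6 arrays without PKA, the labelled split called 0 genes, and all 10 possible splits reached at least that. The highest other split called 92 and set the libraries numbered 1 of CJM571 with the ethanol library of CJM569 against the rest. With 10 splits no share under 0.05 was possible. For CJM571 against CJM567 over 8 arrays, 2 of 35 splits reached the 32 genes of the strain split, and the other was the split by replicate number, with 248 genes, which points to the structure of the samples.

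TPK2 read 27.5 and 27.1 in the libraries numbered 2 of CJM567 and 319 to 566 in the other 8 libraries. HIS3 read 1832 and 1375 in those 2 libraries and 388 to 899 in the others. The a-specific genes STE2 and BAR1 read 377 and 379, and 284 and 449, in the same 2 libraries. In the libraries numbered 1 of CJM567 they read 58.9 and 47.6, and 44.0 and 65.1. Both also lay higher after glucose in CJM569, STE2 at 170 against 56 in ethanol and BAR1 at 266 against 115. A rise of these genes is therefore not particular to those 2 libraries.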
